A study of Drosophila melanogaster with 20 samples.

How the data were processed

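RNA levels were measured in Drosophila SL2 cells, a line derived from embryos that resembles blood cells, on Affymetrix Drosophila Genome 2.0 arrays. Cells were either left untreated or given double-stranded RNA (dsRNA) against SPS1, selenophosphate synthetase 1, and were harvested on day 1, 3 or 5. The dsRNA was added to the medium of plated cells, which were split after 24 hours, per the labels' protocols. Untreated cells received no dsRNA, so an effect of dsRNA as such cannot be separated from an effect of SPS1 loss. Groups came from the sample titles. The source field of the day 5 knockdown samples reads as untreated, while their titles and descriptions name SPS1 dsRNA, and the titles were used.

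The deposited table holds log2 values from RMA, per the submitters' processing notes. The RMA version and the probe annotation it used are not given in the sources used here. The table has 18952 probe sets on 20 arrays, with log2 values from 2.475 to 14.359. Array medians lay between 4.53 and 4.69, and sorted columns differed by at most 0.398, so the authors' values were taken as already normalized between arrays and were used without further scaling. RMA compresses changes of weakly expressed genes toward 0, so their folds are understated. The number of arrays limits the precision.

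After 183 control probe sets were left out, 18769 were tested. Of these, 13647 had 1 gene symbol, 402 had several and 4720 were unnamed in the platform annotation used here. Entrez identifiers of 13544 probe sets matched the RefSeq gene table of the Release 6 plus ISO1 MT assembly, and 0 symbols differed after the match. The named probe sets covered 11982 genes. Coordinates are not printed, because the build behind the array design is not given in the sources used here. No probe set carried the name Sps1 (also known as SelD), the gene targeted here, so its level is not reported and the knockdown was not measured by name.

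The 2 technical arrays, 1 in each day 3 group, were averaged with biological replicate 2 of their group. This left 18 samples: 5 untreated and 5 knockdown at day 1, and 2 untreated and 2 knockdown at each of days 3 and 5. Which culture a technical array repeats was taken from its number. Each lay closer to replicate 2 of its group (root mean square difference 0.188 log2 units untreated, 0.172 knockdown) than to replicate 1 (0.33 and 0.338), and other assignments were tried. In both technical arrays the actin probes at the 3′ end exceeded those at the 5′ end by more (1.24 log2 units untreated, 1.04 knockdown) than in any biological array (0.12 to 0.54).

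All 6 groups entered 1 linear model in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation (12 residual and 4.26 prior degrees of freedom). Benjamini-Hochberg adjustment ran over all tested probe sets, and adjusted p under 0.05 counted as a change. The knockdown was compared with untreated cells within each day, these changes were compared between days, and untreated cells were compared between days. Standard errors (SE) come from this model. Because all groups share 1 estimate of the spread, tests at days 3 and 5 with 2 samples per group borrow most of it from the 10 samples of day 1. Each adjusted p below is from limma unless another tool is named.

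Replicate numbers recur in both groups of a day. Deviations from the group means correlated between same-numbered samples at r from 0.69 to 0.84 in the 5 day 1 pairs, across probe sets with mean log2 above 6, and in each of these the own number correlated best. At days 3 and 5 r was 0.78 and 0.71, 1 value per day, because with 2 samples per group both pairs of a day have the same r. The labels do not say what a number marks, so the pairing comes from the data. The main fit counts spread shared within a pair as error, which can make its p-values too large where pairs vary together. A second fit with day and replicate number as a block (6 residual degrees of freedom) is given beside calls of results printed here that it changes and counts it moves by over 1.5 times.

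The 27 gene lists were fixed before the data were examined: selenium pathway, vitamin B6 metabolism, PLP-dependent enzymes (pyridoxal phosphate, the active form of vitamin B6), glutamine, glutamate and proline metabolism, amino acid transporters, ATF4 and one-carbon response, antimicrobial peptides, Imd and Toll pathway, JAK-STAT and JNK pathway, glutathione S-transferases, redox defence, heat shock, ER stress, glycolysis, TCA cycle and oxidative phosphorylation, mitochondrial dynamics, cell cycle, apoptosis, ribosome biogenesis, proteasome, RNA interference, ecdysone response, extracellular matrix, plasmatocyte markers, crystal cell and lamellocyte markers, markers of neuron, muscle and fat body, and ribosomal proteins. Each gene was represented by its probe set with the highest mean. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 81 combinations of list and day. The fry test asks whether a list's genes move on balance one way, and unlike camera does not compare them with other genes. No list passed on any day with an estimated correlation. Some list members, among them DptA and AttA, had no probe set of that name here.

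Genes are named by a rule fixed likewise. At each day these are the 10 largest rises and 10 largest falls among probe sets with 1 symbol, adjusted p under 0.05 and every knockdown sample beyond every untreated one. For each difference between days the 5 largest in each direction past the threshold are named. Sps2 is named throughout, and from each list up to 4 members with the smallest adjusted p, whether or not they passed. A single unnamed probe set was chosen after its values were seen.

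The fit and the list test were tested on simulated values with known changes (log2 scale). With changes planted among 18769 probe sets, 100% of those of 1 log2 unit were recovered at day 1, 86.6% at day 3 and 83.6% at day 5. For changes of 0.5 log2 units the shares were 92.5% at day 1, 28.4% at day 3 and 31.3% at day 5. False calls made up 5.8%, 5.4% and 7.1% of the calls at days 1, 3 and 5. All these shares are for the fit, not for the list test. The simulation held no pairing and no differences in spread between days. Alternatives covered scaling, a filter on low values, separate fits per day, the variance prior, array weights, the block, the technical arrays, thresholds, a plain test per day and each sample left out. Counts and lists were refitted without each of the 18 samples, and single genes without each sample of the days compared. At days 3 and 5 such a refit leaves 1 sample in a group, so its calls rest mostly on the spread of other groups. A further alternative, adding 16 before the log, was not run because the values were already log2. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.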

Results

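Gene expression in SL2 cells given SPS1 dsRNA was compared with that in untreated cells on days 1, 3 and 5, to find genes regulated directly or secondarily by SPS1. Because untreated cells received no dsRNA, a change cannot be assigned to SPS1 loss rather than to dsRNA. Whether a change was direct was not tested. SPS1 is related to the enzyme that makes selenophosphate. The comparison used 18 samples from 20 arrays, with 5 samples per group at day 1 and 2 per group at days 3 and 5. The labels call the samples biological replicates and say nothing of separate transfections, so p-values measure only the spread between these samples, which may be technical.

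At day 1 no named gene passed the threshold. The library labelled untreated, day 1 replicate 4 lay apart from its group. An unnamed probe set, chosen after its values were seen, measured 9.46 there, against 11.53 ± 0.07 (SD, n = 4) in the other untreated samples and 8.73 to 9.44 in the knockdown samples. For sgll, which encodes the oxidase that makes the active form of vitamin B6, that library measured 7.76, against 8.45 to 8.70 in the other untreated samples and 7.64 to 8.14 in the knockdown. Day 1 comparisons therefore set the knockdown against a group that holds this library. With it, 0 of 18769 probe sets passed in limma and 290 had an unadjusted p under 0.05, where chance alone gives 938.5. In the fit with the replicate block 0 passed and 1000 had an unadjusted p under 0.05, and a plain test within the day also gave 0. Without that library 1 probe set passed, the unnamed one, which fell by 2.37 on the log2 scale (5.17-fold, SE 0.16, adjusted p = 4.8e-06), but its own value had singled that library out, so this p is no independent evidence. The change of sgll was then -0.71 (adjusted p = 0.33).

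**Figure D1:**
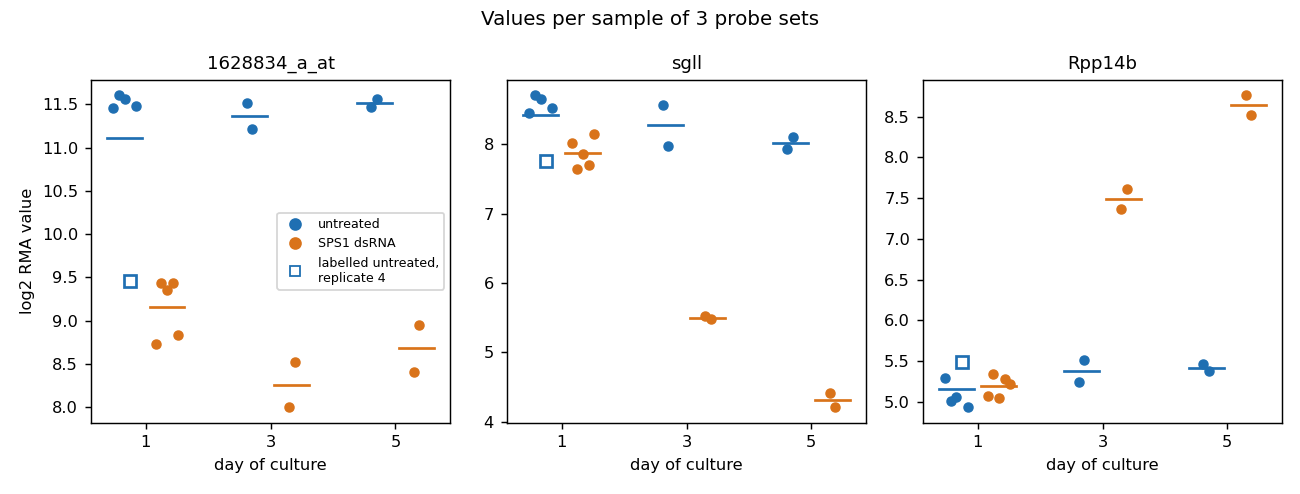
Values per sample of 3 probe sets, as log2 RMA values against the day of culture, with untreated samples in blue, SPS1 dsRNA samples in orange, each point 1 sample and each bar a group mean over all its samples. The open square is the library labelled untreated, day 1 replicate 4, which for the unnamed probe set, in the panel titled with an array identifier, lies at 9.46, away from the other untreated samples at 11.46 to 11.61.

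Of the gene lists, vitamin B6 metabolism and the proteasome lay lower at day 1 with the preset correlation (adjusted p = 0.0058 and 0.021), and with an estimated correlation adjusted p = 0.13 and adjusted p = 0.86. With fry these were 0.036 and 0.98. None of the 9 and 28 measured members passed, and adjusted over the list alone 1 and 0 did. In the first list the log2 changes were -0.55 for sgll, -0.22 for CG31473, -0.18 for CG5577 and -0.15 for CG11291. In the proteasome list they were -0.09 for Pomp and -0.07 for Prosalpha6, Prosalpha4 and Rpn7. Without untreated replicate 3, or without knockdown replicate 1, 1 list passed. Sps2, the selenophosphate synthetase that is itself a selenoprotein, was at 0.08 (SE 0.19, adjusted p = 1).

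At day 3 the gene sgll fell by 2.77 on the log2 scale (6.82-fold, SE 0.25, adjusted p = 6.8e-05), from 8.27 ± 0.42 to 5.50 ± 0.03 (SD, n = 2 each). Rpp14b, a protein component of ribonuclease P, rose by 2.12 (4.33-fold, SE 0.17, adjusted p = 1.5e-05), from 5.38 ± 0.19 to 7.49 ± 0.17. The other falls were in pst (-2.12), a gene of antiviral defence, CG32985 (-2.07), CG1572 (-1.90), CG10063 (-1.76), gammaTub37C (-1.74), the gamma-tubulin of the female germline, CG4210 (-1.67), CG33462 (-1.67), CG32280 (-1.55) and cDIP (-1.51), with adjusted p from 0.00011 to 0.032. CG46491 (1.06), egr (0.94 and 0.84 at its 2 probe sets), the tumour necrosis factor ligand Eiger, and CG9154 (0.81, adjusted p = 0.048) completed the rises. For egr, untreated cells of day 3 were lower than those of day 1 (-0.75, adjusted p = 0.017, and -0.57, adjusted p = 0.035), and knockdown cells went from 8.37 to 8.59 at the first probe set. The unnamed probe set fell by 3.10 (8.6-fold, SE 0.52, adjusted p = 0.019), from 11.37 ± 0.21 to 8.26 ± 0.37 (SD, n = 2 each). Its SE draws on the untreated day 1 samples, whose SD was 0.93 with the library labelled untreated, day 1 replicate 4 included. Sps2 was at -0.03 (SE 0.30, adjusted p = 1).

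In all, 33 probe sets passed at day 3, 5 higher and 28 lower, in 27 named genes. The replicate block raised this to 234, 68 higher and 166 lower, including all 33. Without the block 633 had an unadjusted p under 0.05 in limma, where chance alone gives 938.5, and with it 1863 did. Rpp14b, sgll, CG1572 and CG32280 kept their calls with any 1 day 3 sample left out, and the other 10 genes named above lost theirs in at least 1 such fit, as did the unnamed probe set in all 4 (adjusted p from 0.062 to 0.15). The change of pst was -1.45 without untreated replicate 1 (adjusted p = 0.18) and -2.79 without untreated replicate 2. With cyclic loess 11 of 41 were higher. Fitted from day 3 alone, 0 passed, as with a plain test, and leaving out 1 day 3 sample gave 13 without untreated replicate 2, 11 without knockdown replicate 2 and 21 without knockdown replicate 1. Averaging the technical arrays with replicate 1 instead gave 72.

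With the preset correlation 8 lists passed at day 3, against 3 without knockdown day 3 replicate 2 and 5 when knockdown replicate 1 or replicate 2 of day 5 was left out. Antimicrobial peptides lay higher with 0 of 15 members past the threshold, 1 adjusted over the list alone (adjusted p = 0.021; adjusted p = 0.38 with an estimated correlation). Members with the smallest p were edin (1.10), Mtk (1.67), DptB (0.87) and AttD (0.55). With the replicate block edin, Mtk and DptB passed (adjusted p = 0.031, 0.014 and 0.024), and AttD lay between -0.18 and 1.28 with 1 day 3 sample left out. Plasmatocyte markers lay higher with 0 of 18 passing, 0 adjusted over the list alone, with Pxn at 0.62 and Hml at 0.57 (adjusted p = 0.021; adjusted p = 0.51 with an estimated correlation). With 1 day 3 sample left out Pxn lay between -0.12 and 1.36 and Hml between -0.058 and 1.21. The RNA interference list lay lower, and 1 of its 21 members fell, aub (-1.21, adjusted p = 0.048), with 2 adjusted over the list alone (adjusted p = 0.00018; adjusted p = 0.24 with an estimated correlation). Beside aub, a Piwi protein, spn-E was at -0.76, Hen1 at -0.57 and armi at -0.53, and with the replicate block aub, spn-E and Hen1 passed. Lower lists with 0 members past the threshold, 0 also adjusted over the list alone, were glycolysis (adjusted p = 0.00014; adjusted p = 0.38 with an estimated correlation), heat shock (adjusted p = 0.00011; adjusted p = 0.13 with an estimated correlation) and ribosome biogenesis (adjusted p = 0.036; adjusted p = 0.86 with an estimated correlation). In glycolysis Pgm1 was at -1.26, Gpdh1 at 0.30 and fbp at -1.40, and with the replicate block 3 members were called lower, among them Pgm1 and fbp. In the heat shock list Hsp26 was at -0.93, stv at -0.87 and Hsp27 at -0.71, and with the replicate block stv and Hsp27 passed. In vitamin B6 metabolism 1 of 9 members fell, sgll, 1 adjusted over the list alone (adjusted p = 0.031; adjusted p = 0.24 with an estimated correlation). Of 36 glutathione S-transferases 1 fell, GstD5 (-0.97, adjusted p = 0.019), 1 adjusted over the list alone (adjusted p = 0.042; adjusted p = 0.78 with an estimated correlation). For GstD5, untreated cells of day 3 were higher than those of day 1 (1.15, adjusted p = 0.0014). Both aub and GstD5 lost their calls with 1 day 3 sample left out. Vitamin B6 metabolism and the glutathione S-transferases did not pass with the replicate block (adjusted p = 0.2 and 0.32), and with fry 2 lists passed, heat shock (adjusted p = 0.031) and vitamin B6 metabolism (adjusted p = 0.0066). Extracellular matrix passed with the replicate block, higher, with 1 member called there (adjusted p = 0.003; adjusted p = 0.53 with an estimated correlation).

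At day 5 genes of antimicrobial defence had the largest rises. Mtk, which encodes metchnikowin, rose by 4.57 (23.8-fold, SE 0.68, adjusted p = 0.00073), from 5.64 ± 0.85 to 10.21 ± 0.19 (SD, n = 2 each). Next came edin (3.64), AttD (3.37), an attacin, eater (3.28), a phagocytic receptor, Rpp14b (3.22), DptB (3.13), a diptericin, CG4259 (2.94), CG4250 (2.75), Nepl4 (2.69), a neprilysin-like gene, and CG13077 (2.57), with adjusted p from 2.4e-08 to 9e-04. CG32985 fell by 3.83 (14.2-fold, SE 0.37, adjusted p = 1.6e-05) and sgll fell by 3.71 (13.1-fold, SE 0.25, adjusted p = 3.6e-07). They were followed by CG1572 (-3.31), Ids (-3.25), a lysosomal sulfatase, CG3625 (-3.14), Mctp (-2.98), CG34008 (-2.92), jtb (-2.82), CG4210 (-2.69) and Karl (-2.61), a lipocalin, with adjusted p from 5e-08 to 0.012. The untreated mean of eater, 3.85, lay at the lower quartiles of the arrays (3.72 to 3.86), and the knockdown mean of sgll, 4.31, below the array medians, where RMA understates changes. Another probe set of Mctp, at a mean log2 of 3.46, was at 0.03. The unnamed probe set fell by 2.84 (7.14-fold, SE 0.52, adjusted p = 0.0041), from 11.52 ± 0.062 to 8.68 ± 0.385 (SD, n = 2 each), with the same spread behind its SE as at day 3. Sps2 was at 0.05 (SE 0.30, adjusted p = 0.98). On each of the 3 days leaving out some single sample turned the direction of Sps2.

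At day 5, 523 probe sets passed, 224 higher and 299 lower, in 449 named genes, and 216 of them changed at least 2-fold. The replicate block raised this to 2293, 952 higher and 1341 lower, including all 523. Fits with 1 day 5 sample left out have 1 culture in that group, so calls kept there rest mostly on the spread of other groups. Of the 20 genes named above, 19 kept their calls with any 1 day 5 sample left out, and Ids lost its call without untreated replicate 1 or 2 or knockdown replicate 1. The unnamed probe set lost its call without knockdown replicate 1 (adjusted p = 0.067). That library stood apart, as the 12 largest of the 190 differences between arrays all involved it (root mean square 0.436 to 0.506 log2 units), and several falls were smaller without it and larger without knockdown replicate 2: CG32985 (-2.95 and -4.71), CG3625 (-2.53 and -3.75), CG34008 (-2.12 and -3.72), Mctp (-2.01 and -3.95), jtb (-1.63 and -4.0) and Karl (-1.63 and -3.59). So the place of CG32985 as the largest fall rests on that library. For these falls the knockdown samples of day 5 had SDs from 0.865 (CG3625) to 1.678 (jtb), with 1.24 for CG32985. All were larger than the SDs of the same genes at day 1, which for CG32985 were 0.195 untreated and 0.243 knockdown. The SE and adjusted p of these falls rest mostly on the day 1 samples. They therefore understate the spread between the day 5 knockdown samples. Mtk rose by 3.97 without untreated replicate 1 and by 5.17 without untreated replicate 2. With each array's median subtracted 152 of 471 were higher. Fitted from day 5 alone 81 passed and a plain test gave 2, while leaving out untreated replicate 1 gave 264, untreated replicate 2 gave 271 and knockdown replicate 1 gave 273.

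**Figure D2:**
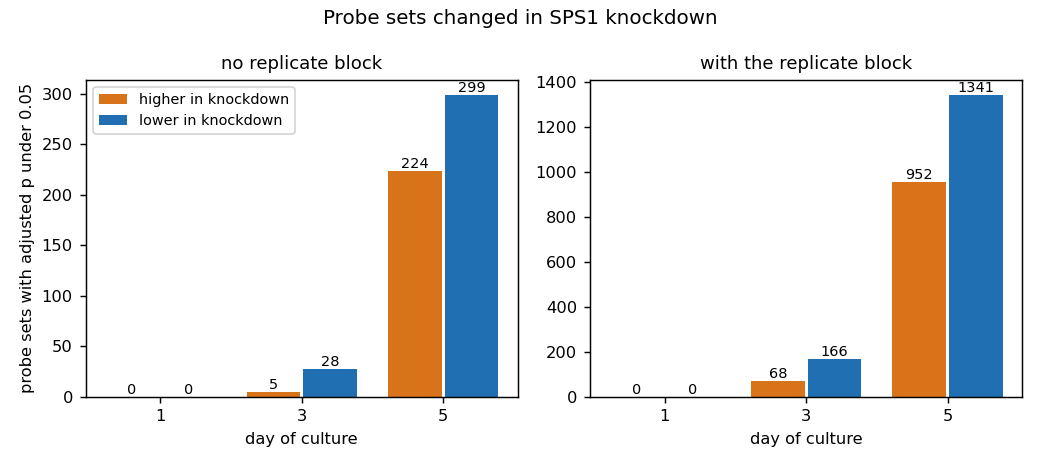
Number of probe sets with adjusted p under 0.05 against the day of culture, higher in SPS1 knockdown in orange and lower in blue, without the replicate block on the left and with it on the right. The 2 panels have different vertical scales: 523 probe sets passed at day 5 without the block and 2293 with it.

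Of the 15 measured antimicrobial peptide genes 5 rose at day 5, 5 also adjusted over the list alone: Mtk, edin, DptB, AttD and CecB (2.23), a cecropin (list adjusted p = 1.6e-07; adjusted p = 0.11 with an estimated correlation). In the Imd and Toll pathway 6 of 29 rose, 6 adjusted over the list alone, with 2 lower there, and with the replicate block 9 were called higher and 2 lower (list adjusted p = 0.029; adjusted p = 0.24 with an estimated correlation). The 6 included pirk (1.86), PGRP-LF (1.93) and PGRP-LB (0.86), which restrain Imd signalling, and the receptor Tl (0.79). Of 18 plasmatocyte markers 4 rose, 5 adjusted over the list alone: eater, Pxn (2.35), drpr (1.21) and Tig (0.94) (list adjusted p = 0.00025; adjusted p = 0.24 with an estimated correlation). In the extracellular matrix list 7 of 27 rose, 9 adjusted over the list alone, among them Pxn, if (1.12), LanB1 (1.07) and Plod (1.04), and with the replicate block 10 were called higher and 2 lower (list adjusted p = 9.8e-05; adjusted p = 0.31 with an estimated correlation). Of 16 genes of glutamine, glutamate and proline metabolism 3 rose, 4 adjusted over the list alone: Oat (1.63), ornithine aminotransferase, Gs1 (1.51), a glutamine synthetase, and Gdh (0.59), glutamate dehydrogenase, with 7 called higher with the replicate block (list adjusted p = 0.00017; adjusted p = 0.24 with an estimated correlation). Of 36 glutathione S-transferases 3 rose, 7 adjusted over the list alone: GstD4 (0.90), GstD7 (0.74) and GstD5 (0.70), with 10 called higher with the replicate block (list adjusted p = 0.00042; adjusted p = 0.54 with an estimated correlation). These GstD genes are close paralogs whose probe sets can share signal. With fry the glutathione S-transferases did not pass (adjusted p = 0.25). In at least 1 fit with 1 day 5 sample left out PGRP-LB, drpr, Tig, Gs1, Gdh and the 3 GstD genes lost their calls, and CecB was at 1.60 without knockdown replicate 1 and 2.87 without replicate 2.

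Other lists lay lower at day 5. In the cell cycle list 4 of 44 members fell, 12 adjusted over the list alone and 18 with the replicate block: PCNA (-0.50), borr (-0.52), Orc2 (-0.43) and Mcm2 (-0.36) (list adjusted p = 1.4e-07; adjusted p = 0.25 with an estimated correlation). In ribosome biogenesis 0 of 34 passed, 5 adjusted over the list alone and 22 with the replicate block, with Polr1A at -0.39 and Nop60B at -0.33 (list adjusted p = 2.6e-06; adjusted p = 0.54 with an estimated correlation). Of 28 proteasome genes 0 passed, 0 adjusted over the list alone and 9 with the replicate block, with Prosbeta5 at -0.44 (list adjusted p = 0.00018; adjusted p = 0.75 with an estimated correlation). In the RNA interference list 3 of 21 fell, 4 adjusted over the list alone: armi (-1.24), Hen1 (-1.20) and aub (-1.17), which act in small RNA pathways, while eater, also among the plasmatocyte markers, rose; with the replicate block 8 were called lower (list adjusted p = 0.0025; adjusted p = 0.31 with an estimated correlation). With fry ribosome biogenesis (adjusted p = 0.16) and the proteasome (adjusted p = 0.33) did not pass. The falls were smaller after cyclic loess scaling. The median change went from -0.24 to -0.17 for the cell cycle and from -0.32 to -0.24 for ribosome biogenesis. For the proteasome it went from -0.19 to -0.12, and for RNA interference from -0.27 to -0.2. In at least 1 fit with 1 day 5 sample left out Hen1, aub and the 4 cell cycle genes lost their calls.

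The other 17 lists did not pass at day 5 (adjusted p from 0.071 to 0.91 with the preset correlation), although single members did, and with fry vitamin B6 metabolism (adjusted p = 0.0037) and JAK-STAT and JNK (adjusted p = 0.031) passed, a test against no change and not against other genes, with a median change of 0 in both. In glycolysis Gpdh1 rose (1.22) and Pgm1, phosphoglucomutase, fell (-2.48), and the list passed with the replicate block, lower (adjusted p = 0.003; adjusted p = 0.6 with an estimated correlation). Among PLP-dependent enzymes Cbs, cystathionine beta-synthase, fell (-1.77) and Oat rose, and in vitamin B6 metabolism sgll fell with the next member, CG5567, at -0.30. Catalase, Cat, rose (1.35) and Gclm fell (-0.39) in redox defence. In apoptosis egr (1.29, and 1.51 at its other probe set; untreated day 5 minus day 1 -0.62, adjusted p = 0.012, and -0.53, adjusted p = 0.098) and Dronc (0.54) rose and Debcl fell (-1.16), and in the JAK-STAT and JNK list Tep4 (1.13) rose with egr. Sesn (1.53) and aay (0.62) rose in the ATF4 and one-carbon list, CG13384 (0.75) rose and CG5535 fell (-2.60) among amino acid transporters, MsrA rose (1.04) in the ecdysone list, and RpS10a fell (-1.24) among ribosomal proteins. Without the replicate block no member passed in the selenium pathway (0 of 9), heat shock (0 of 19), ER stress (0 of 24), TCA cycle and oxidative phosphorylation (0 of 51), mitochondrial dynamics (0 of 22), crystal cell and lamellocyte markers (0 of 15) or markers of neuron, muscle and fat body (0 of 17). With the block, members called higher and lower were 1 and 2 in the selenium pathway, in heat shock and in mitochondrial dynamics, 2 and 3 in ER stress, 0 and 1 in the TCA list, 0 and 3 among crystal cell markers, and 1 and 0 in the last list. They were 1 and 4 in glycolysis, 4 and 3 among PLP-dependent enzymes, 0 and 2 in vitamin B6 metabolism, 4 and 2 in redox defence, 3 and 2 in apoptosis, 3 and 1 in JAK-STAT and JNK, 5 and 2 in the ATF4 list, 2 and 1 among amino acid transporters, 1 and 1 in the ecdysone list and 0 and 2 among ribosomal proteins. Single members were refitted only where the naming rule, up to 4 per list, picked them. Of the 39 list members so named that passed at day 5 and are not among the 20 genes with the largest changes, 19 kept their calls with any 1 day 5 sample left out, among them CecB, pirk, Pxn, LanB1, Oat, armi, Gpdh1, Cbs, Cat and egr. The other 20 lost theirs in at least 1 such fit, Pgm1, Gclm, Sesn, aay, MsrA and RpS10a and the 14 given with their lists above. Without knockdown replicate 1 and without replicate 2, CG5535 was at -1.64 and -3.56 and Pgm1 at -1.86 and -3.10. Adjusted over the list alone, 2 members of the selenium pathway were lower and 1 of the neuron, muscle and fat body markers was higher.

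**Figure D3:**
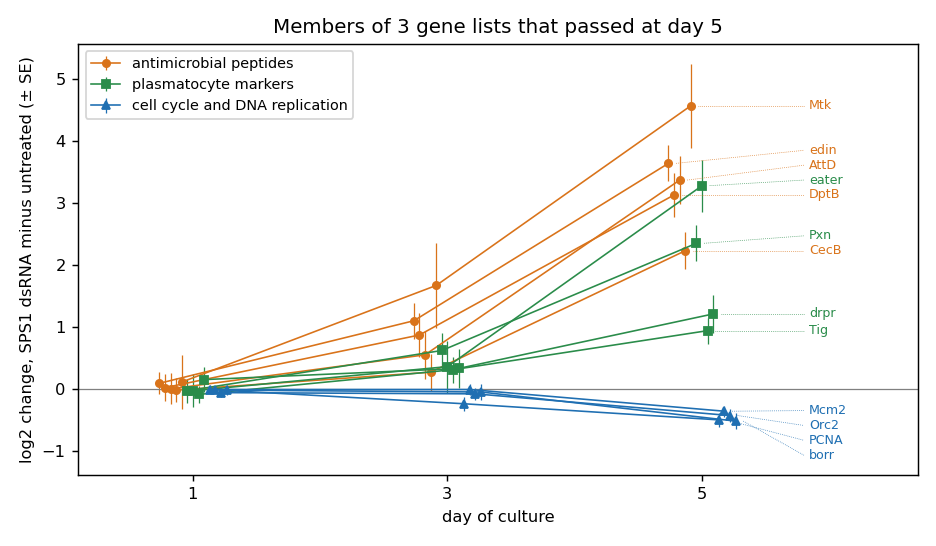
Log2 change between SPS1 dsRNA and untreated samples with its SE against the day of culture, shown for members of 3 lists that passed at day 5, with points shifted sideways within a day for legibility. Antimicrobial peptide genes lie near 0 at day 1, and at day 5 Mtk is at 4.57 and CecB at 2.23.

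The days were then compared with each other, to separate early from late changes. Of the 33 probe sets called at day 3, 29 were also called at day 5, 4 higher on both days, 24 lower on both and 1 opposite. Independent calls would share 0.06 higher and 0.45 lower, but the calls of both days rest on 1 shared estimate of the spread and are not independent. The opposite one was GstD5. The log2 changes of days 3 and 5 correlated at r = 0.56 across all probe sets, which are not independent replicates. Of the 33, 30 had the same direction at day 1. For the day 3 calls the median absolute change was 0.15 at day 1, 1.21 at day 3 and 1.72 at day 5. Shared calls in the same direction numbered 192 with the replicate block, 0 with each day fitted alone, 9 without untreated day 3 replicate 2, 10 without knockdown day 3 replicate 2, 14 without knockdown day 3 replicate 1 and 18 without untreated day 3 replicate 1.

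The knockdown change differed between day 5 and day 1 for 263 probe sets, 126 more positive and 137 more negative at day 5. The untreated day 1 group here holds the library labelled untreated, day 1 replicate 4, which resembled the knockdown. With that library the day 1 change of sgll was -0.55, and without it -0.71, so differences from day 1 can be overstated. The largest differences were Mtk (4.46), edin (3.55), AttD (3.37), eater (3.32) and Rpp14b (3.19) upward, and CG32985 (-3.58), sgll (-3.16), CG3625 (-3.02), CG34008 (-2.99) and Mctp (-2.88) downward, with adjusted p from 3.9e-07 to 0.012. Of these 10 genes 8 kept their calls with any 1 sample of these days left out, and Mtk and Mctp lost theirs without some single day 5 samples. Without knockdown day 5 replicate 1 and without replicate 2 the differences were -2.70 and -4.46 for CG32985, -2.41 and -3.63 for CG3625, -2.19 and -3.79 for CG34008 and -1.91 and -3.85 for Mctp. For Mtk they were 3.86 and 5.07 without untreated day 5 replicate 1 and replicate 2. The adjusted p for CG32985, CG3625, CG34008 and Mctp again understate the spread between the day 5 knockdown samples. The count was 1280 with the replicate block and 167 without both replicate 4 samples of day 1. It was 112 without untreated day 5 replicate 1, 144 without untreated day 5 replicate 2, 145 without knockdown day 5 replicate 1 and 400 without knockdown day 5 replicate 2. Between day 3 and day 1 the change differed for 4 probe sets, Rpp14b (2.08), egr (0.87, and 0.97 with adjusted p = 0.08 at its other probe set, with the called fall in untreated cells given above), sgll (-2.22) and CG32280 (-1.47), of which Rpp14b kept its call with any 1 sample of these days left out, and with the replicate block for 63. That count was 1 without knockdown day 3 replicate 2, 8 without untreated day 3 replicate 1, 11 without knockdown day 3 replicate 1 and 10 when knockdown replicate 1 or replicate 2 of day 5 was left out. With each array's median subtracted 1 of 3 was more positive. Between day 5 and day 3 it differed for 18, 17 of them more positive at day 5, led by edin (2.54), pirk (2.46), CG14253 (2.20), CG4250 (2.17) and CG6231 (1.99). Nnf1b, a kinetochore gene, was the 1 more negative (-1.38), and none of these 6 genes kept its call with each sample of these days left out in turn. The replicate block gave 225, and leaving out 1 sample gave 0 (untreated day 5 replicate 1), 5 (untreated day 3 replicate 2), 9 (untreated day 5 replicate 2), 11 (knockdown replicate 1 of day 3 or of day 5), 42 (untreated day 3 replicate 1) and 60 (knockdown day 5 replicate 2).

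Untreated cells were compared over time in the same fit, whose day 1 group again holds the library labelled untreated, day 1 replicate 4. Between day 3 and day 1, 20 probe sets differed, 15 higher and 5 lower at day 3, and between day 5 and day 1, 35 differed, 14 higher and 21 lower at day 5. With each array's median subtracted the latter were 18, of which 12 were higher. Both counts rest on few samples. That for day 3 was 5 without untreated day 3 replicate 2 and 92 without untreated day 3 replicate 1, 33 without knockdown day 3 replicate 1 or replicate 2, and 6 to 12 without most single day 1 samples. That for day 5 was 1 without untreated day 5 replicate 2, 6 without untreated day 5 replicate 1, 15 to 22 without any 1 untreated day 1 sample and 68 when untreated replicate 1 or replicate 2 of day 3 was left out. Sps2 was at -0.18 for untreated cells of day 5 minus day 1 (SE 0.25, adjusted p = 0.86).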

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

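Tests of the explanations below were chosen after the results were seen, except the count of other splits of the day 1 samples. Of 72 groups of 5 tested for a sample far from the others, 8 had one, where chance gives about 3.6. In 5 of them it was the library labelled untreated, day 1 replicate 4, below its group: an unnamed probe set at 9.46, sgll at 7.76, pst at 9.60, CG32985 at 9.12 and Mctp at 7.96. In the other 3 it was knockdown day 1 replicate 5, above its group: CG34008 at 8.53, egr at 9.95 and Nnf1b at 8.21. All 72 groups come from the same day 1 samples, so 1 odd library can raise several flags. The unnamed probe set was chosen after its values were seen. The count of 8 against 3.6 is therefore no independent evidence.

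The library labelled untreated, day 1 replicate 4 resembled the knockdown libraries. On 27 probe sets called in the same direction at days 3 and 5, without the unnamed one, its position was 1.2 on a scale from the other untreated libraries (0) to the knockdown (1), where those untreated libraries lay between -0.19 and 0.32 and the knockdown between 0.65 and 1.5. Among these probe sets are those of sgll and CG32985, on which the library was already flagged, so its position partly repeats those values. A swap with a knockdown-labelled library of day 1 is argued against, as 0 of the 5 lay below 0.5, and so is a batch shared by replicates 2, 3 and 4, since the higher of untreated replicates 2 and 3 was at -0.04. A wrong sample under that label may account for it. Of the 190 array pairs, the smallest difference was between it and knockdown day 1 replicate 4 (root mean square 0.074 log2 units). The other same-numbered pairs of day 1 were also close, at 0.113 to 0.14. The technical pairs, whose technical arrays had the larger actin excess at the 3′ end, lay at 0.172 and 0.188. Whether the culture itself varied was not tested.

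No probe set passed the threshold at day 1. The adjusted p of the unnamed probe set was 4.8e-06 without the library labelled untreated, day 1 replicate 4, which its own value there had singled out, so this p decides nothing. Changes of other probe sets hidden by that library, or by the spread between same-numbered replicate sets, stay open: 0 others passed without it (328 at an unadjusted p under 0.05 in limma) and 0 passed with the replicate block (1000), but the positions of the knockdown libraries lay apart from those of the 4 other untreated ones. Of the 126 splits 100 were drawn, and all 100 have at least the real count, since it is 0, so they decide nothing about chance. The 8 other drawn splits that part all 5 pairs, as the real one does, gave 0. Calls came from 5 of the drawn splits, the highest 545, and each of these set replicates 1 and 5 of both groups, with 1 further sample, against the rest, which points to a structure that follows the replicate numbers.

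Antimicrobial peptide genes were higher at day 5. A fall in the untreated cultures over time is argued against as the whole cause: the 5 risen genes had a median log2 change of 2.94 in knockdown cultures from day 1 to day 5, against -0.56 in untreated cultures. A response to double-stranded RNA itself cannot be told apart from an effect of SPS1 loss, because the controls received no dsRNA. The median knockdown change of these genes was 0.02 at day 1 and 0.87 at day 3, and a slow response may look the same. An effect of SPS1 loss stays open as well.

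The knockdown change differed between days by a test of the difference itself for 4 probe sets (day 3 and day 1), 263 (day 5 and day 1) and 18 (day 5 and day 3). Between day 3 and day 1 these included Rpp14b (2.08), egr (0.87, and 0.97 with adjusted p = 0.08 at its other probe set), sgll (-2.22) and CG32280 (-1.47). Between day 5 and day 1 the differences were Mtk (4.46), edin (3.55), AttD (3.37), eater (3.32), Rpp14b (3.19), CG32985 (-3.58), sgll (-3.16), CG3625 (-3.02), CG34008 (-2.99) and Mctp (-2.88). Between day 5 and day 3 they were edin (2.54), pirk (2.46), CG14253 (2.20), CG4250 (2.17), CG6231 (1.99) and Nnf1b (-1.38).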

How the results depend on the processing

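The settings without the replicate 4 pair of day 1 were chosen after the data were seen. The replicate block changed no call of a probe set that passed without it, and the lists it changed are given with the results. Where no reason is given, the cause was not tested. Weakly expressed genes limit what the arrays can show.

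Of 201 gene results, 97 past the threshold, the planned settings left 2439 comparisons the same, made 227 weaker and 79 stronger and turned 3. With 1 sample of the compared days left out they were 878, 143, 7 and 24. A comparison counts as the same if it passed, or missed, as in the main fit, and only the 97 could become weaker. A plain t-test within each day made 77 results weaker, which is every called result of a single probe set at days 3 and 5. Fitting each day alone made 56 weaker. The settings without the replicate 4 pair were run on counts only, not on single genes. Probe sets at day 3 numbered 0 with each day fitted alone or a plain t-test (fewer samples behind the spread), 11 at adjusted p under 0.01, 13 with array weights, 72 with technical arrays averaged with replicate 1, 106 with them separate, 191 with the replicate block without the replicate 4 pair and 234 with the replicate block. At day 5 they numbered 2 with a plain t-test, 81 with each day alone, 216 at 2-fold or more, 285 at adjusted p under 0.01, 301 with array weights, 2081 with the block without that pair and 2293 with the replicate block. At day 1 there was 1 without that pair, with or without the replicate block, shared with days 3 and 5 (1 and 1). Calls shared by days 3 and 5 were 0 with each day alone or a plain t-test, 10 at adjusted p under 0.01, 12 with array weights, 47 and 78 with technical arrays averaged with replicate 1 and separate, 162 with the replicate block without the pair and 192 with the replicate block.

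Differences between day 3 and day 1 were 63 with the replicate block, 28 with it but without the pair, 15 with separate technical arrays and 11 with them averaged with replicate 1. Between day 5 and day 1 they were 1280 and 966 with the replicate block (all samples, without the pair), 167 without the pair, 159 at 2-fold and 129 at adjusted p under 0.01. Between day 5 and day 3 they were 225 and 185 with the replicate block, 75 and 59 with technical arrays averaged with replicate 1 and separate, 11 with medians subtracted, 8 with array weights, and 5 at adjusted p under 0.01 or without the pair. In untreated cells day 3 differed from day 1 for 34 with the filter above 6, 189 with separate technical arrays, 274 with them averaged with replicate 1, 4 at 2-fold, 6 at adjusted p under 0.01 and 9 without the pair. Day 5 differed from day 1 for 55 with cyclic loess, 18 with medians subtracted, 53 with the filter, 54 with array weights, 98 with technical arrays averaged with replicate 1, 7 at 2-fold or at adjusted p under 0.01 and 21 without the pair. Lists passing at day 1 were 1 with cyclic loess, the filter, adjusted p under 0.01 or fry, and 0 with an estimated correlation. At day 3 they were 5 with each day alone, 3 at adjusted p under 0.01, 2 with fry and 0 with an estimated correlation, which also gave 0 at day 5, where fry gave 9.

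With each sample left out in turn, the counts ranged from 0 to 1 at day 1, 11 to 47 at day 3 and 264 to 777 at day 5. They were 1 to 11, 112 to 400 and 0 to 60 for the differences between day 3 and 1, 5 and 1, and 5 and 3, and 5 to 92 and 1 to 68 in untreated cells at days 3 and 5. Shared calls ranged from 0 to 1 for day 1 with either later day and from 9 to 38 for days 3 and 5, and lists from 1 to 3, 3 to 9 and 8 to 11 at days 1, 3 and 5. A sample left alone in its group was assumed to vary like the other groups.

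Results that turned had not passed. Sps2 turned with cyclic loess (0.072, day 5 minus day 1) and with medians subtracted (-0.016, day 5), and Hr4 with the mean of all probe sets (-0.02, day 5). With each sample of the compared days left out in turn Sps2 ranged from -0.021 to 0.18 at day 1, -0.46 to 0.39 at day 3, -0.20 to 0.31 at day 5, -0.54 to 0.32 for day 3 minus day 1, -0.28 to 0.23 for day 5 minus day 1 and -0.34 to 0.51 for day 5 minus day 3. At day 3 the ranges were -0.31 to 1.03 for eater, -0.75 to 0.14 for kra, -1.38 to 0.40 for GstO3, -0.18 to 1.28 for AttD, -0.94 to 0.022 for Hsp68, -0.12 to 1.36 for Pxn and -0.058 to 1.21 for Hml, and at day 5 -0.071 to 0.46 for Mlp60A. A log2(value + 16) setting was not run, since the values were log2 already. The plain t-test and the fit of each day alone give no differences between days, and the block gives none for untreated cells over time.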

Other observations

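The tests of the lists in the next paragraphs were written before their results were seen, but after single genes had drawn attention. Several genes of the female germline or oocyte fell with the knockdown, among them gammaTub37C and aub at day 3, and armi and Hen1 at day 5. The hypothesis that genes of the germline and of the oocyte fall together was tested on 47 measured genes without aub, grk, exu, gammaTub37C, armi and Hen1, which had been seen. At day 5 the list lay lower (camera with an estimated correlation, p = 0.044; p = 0.062 with the preset correlation), with 29 of 47 changes below 0, a median of -0.07, and 3 genes that fell, squ, gnu and papi. This list had been revised before any test, and the version first written, of 49 measured genes, had 31 changes below 0 and gave a camera p of 0.019. Neither version passed after adjustment over all 9 tests of such lists and days, with adjusted p = 0.2 for the revised list and adjusted p = 0.17 for the first. The values are consistent with a small shared shift, which these data do not establish.

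A second hypothesis was that genes of the lysosome rise together, raised by LManI, LManII and Ect3, which rose at day 5. Without these and Ids, 33 measured genes had a median change of 0.10 at day 5, with 23 above 0 and 2 that rose, CtsL1 and Sgsh. The list did not pass (camera, p = 0.1 with an estimated correlation; p = 0.0052 with the preset one). Although a miss had been set beforehand as the result that would exclude the hypothesis, a list that leaves out the called LManI, LManII, Ect3 and Ids cannot exclude it, so it stays open. Ids, a lysosomal enzyme too, fell.

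The unnamed probe set described for day 1 fell at days 3 and 5 (-3.10 and -2.84). It is unnamed in the annotation used here, and whether it belongs to the targeted transcript was not tested.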
